A study of Mus musculus with 6 samples.

How the data were processed

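RNA sequencing of 6 libraries of sorted mouse regulatory T cells was analysed from the FPKM values that the authors deposited. Per the labels' protocols, lymphocytes of lymph node and spleen were enriched for CD4 T cells and sorted, and libraries were made with the SMART-Seq v4 kit for low amounts of RNA. Per the submitters' processing notes, the tools named were Bowtie2 2.2.3, TopHat2 2.0.12 and HTSeq 0.6.1. The notes name the mouse build mm9, and the roles of the tools, the annotation and the strand setting are not given in the sources used here. Without a stated strand setting, reads of overlapping and antisense genes cannot be told apart. One passage of the labels describes both genotypes with the same allele pair, and the genotype of each library was taken from its own genotype label.

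The deposited FPKM were in 2 tables of 47427 and 47347 rows, 47347 of them shared. Of the shared rows, 47069 carried an Ensembl gene ID, and 46488 of these matched a gene symbol and 581 did not. The 278 shared rows with only a running number were left out, since their values correlated at most at r = 0.03 between tables against at least 0.73 within a table. The gene ID and symbol came from a mouse annotation of another build than mm9, so no coordinates are printed. FPKM summed to 625157 to 703317 per library and were not rescaled.

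Depth was estimated because FPKM are not counts. With the mean annotated transcript length as gene length, 77.5% to 79.7% of the values of lowly expressed genes lay within 0.02 of a whole number of fragments, against 3.63% to 4.06% with lengths scrambled. This gave 16.5 to 28.8 M fragments per library. The fragment numbers were used only for counting intervals, which cover counting error alone, and no count test was run.

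Values were tested as log2(FPKM + 1), which understates changes of lowly expressed genes, and genes needed a mean of at least 1 FPKM over the libraries of a fit. Linear models were fitted with limma 3.58.1 in R 4.3.3, with moderated variances that follow a trend with expression, and Benjamini-Hochberg adjusted p under 0.05 counted as passing. Each table held both genotypes, so the table entered as a term in every fit that spanned both. The genotype at 72 h used 4 libraries, and an additive model of genotype, time and table used all 6. An interaction term tested whether the genotype effect differed between times. At 48 h, with 1 library per genotype, log2 ratios were given with no test.

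Gene lists, 24 in all and fixed before the data were examined, were tested with camera and adjusted over the lists. A preset correlation of 0.01 was used, and then an estimated one. The estimated run has only the 1 or 2 residual degrees of freedom of the fit, so a list can hardly pass there. Noc4l was left out of every list, and lists needed at least 5 measured genes. For single pairs of libraries, a list's median was placed among 10000 random lists of the same size matched on mean expression in 20 bins, over genes with a mean of at least 5 FPKM.

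Named genes followed a rule set before the data were examined. Noc4l and 5 regulatory T cell genes were taken in every library. For the genotype at 72 h and for time, the 10 higher and 10 lower genes past the threshold with the largest change and a mean of at least 5 FPKM were taken. Free places were filled with the largest values of the smaller ratio of the pairs, which are values and not calls. For both times together 5 further genes were taken in each direction, and at 48 h the 10 highest and 10 lowest ratios. For each list, 2 to 4 members with the smallest p were named, and predicted genes and clones were not named. A few genes that the rule would name are not reported here. The markers of other cells, the sex-linked genes and the neutrophil genes called when a library was left out were chosen outside this rule.

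The fits were tested on simulated data with 200 changed genes. At 72 h, 2% of genes with a log2 change of 1 and 82% of those with a change of 2 were recovered at adjusted p under 0.05. Over both times 50% and 82% were recovered, and for time 22% and 82%. Noise was drawn separately for each gene, while genes vary together in the data, and the planted genes ease the adjusted threshold. Recovery in the data may thus be lower, and a count of 0 does not show that large changes are absent. Alternatives covered the pseudocount (0.1 and 5), the filter on low values, TPM rescaling, quantile normalization, median centring, the table term, the variance trend, leaving out each library and, for time, the replicate number as a block. Tables and figures used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.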

Results

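Gene expression was measured by RNA sequencing in 6 libraries of mouse regulatory T cells, the CD4 T cell subset defined by the transcription factor Foxp3. The cells carried a Foxp3-driven Cre recombinase and either 1 floxed Noc4l allele (Het) or 2 (cKO, conditional knockout). They were sorted as CD4+GFP+ cells and activated with Dynabeads for 48 h or 72 h. Each genotype had 1 library at 48 h and 2 at 72 h. The replicates were numbered 1 (Het) and 2 (cKO) at 48 h and in a first pair at 72 h, and 3 (Het) and 4 (cKO) in the other 72 h pair. The deposited values were FPKM (fragments per kilobase of gene, scaled to library size) in 2 tables, the first with replicates 1 and 2 and the second with replicates 3 and 4. Estimated depth was 28.8 M fragments for Het and 22.5 M for cKO at 48 h. At 72 h it was 20.9 M (Het 1), 23.9 M (cKO 2), 24.3 M (Het 3) and 16.5 M (cKO 4). Nothing in the labels says whether the libraries came from separate animals or pools, so p-values measure the spread between these libraries.

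Noc4l (ENSMUSG00000033294), whose yeast counterpart acts in assembly of the small ribosomal subunit, was higher in the library labelled cKO in each of the 3 pairs. At 48 h it stood at 99.1 FPKM in Het and 124 in cKO. At 72 h it was 48.8 in Het 1 against 81.7 in cKO 2, and 40.8 in Het 3 against 58.1 in cKO 4. The log2 fold change at 72 h was 0.62 ± 0.14 (SE, 2 libraries per genotype, limma adjusted p = 0.187). The targeted gene thus went against the genotype labels, and every direction below is stated for the libraries as labelled. The tables hold 1 value per gene, so loss of single floxed exons could not be read from them. Foxp3 (ENSMUSG00000039521) was 207 and 225 FPKM in Het and cKO at 48 h, 147 and 173 in replicates 1 and 2 at 72 h, and 278 and 336 in replicates 3 and 4.

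**Figure D1:**
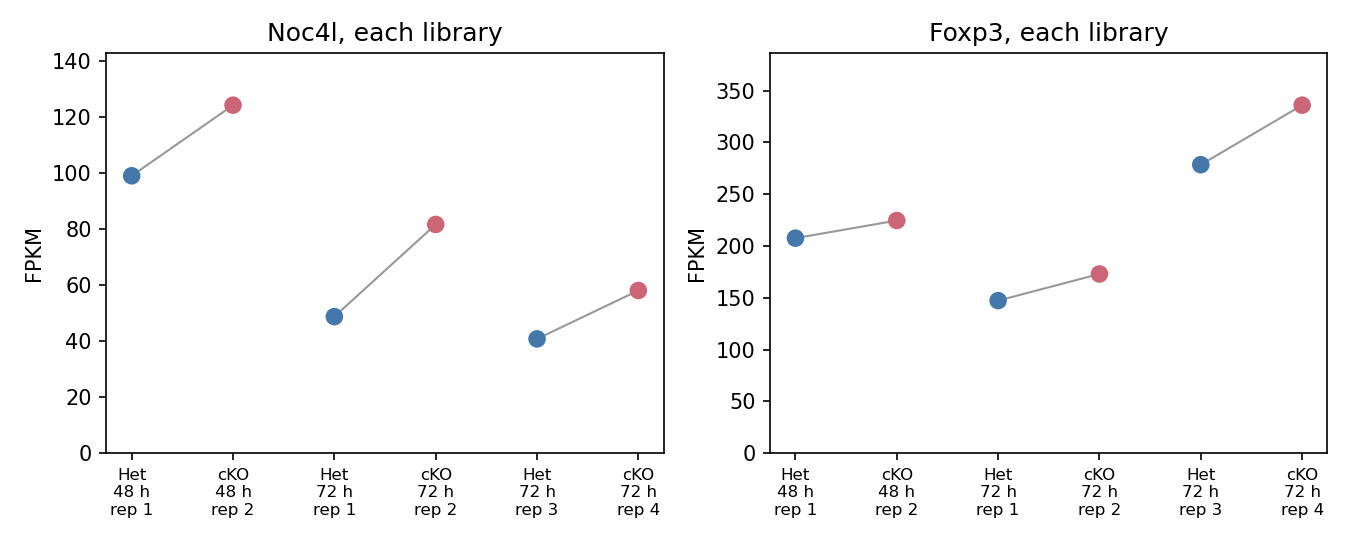
FPKM (linear axis from 0) of Noc4l on the left and Foxp3 on the right in each of the 6 libraries, with Het in blue, the libraries labelled cKO in red, and a line joining each pair. Noc4l is higher in the library labelled cKO in each pair, from 99.1 to 124, 48.8 to 81.7 and 40.8 to 58.1.

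The other regulatory T cell genes set for every library differed little by genotype at 72 h. Il2ra, a subunit of the interleukin 2 receptor, had a log2 fold change of -0.17 ± 0.13 (SE). The inhibitory receptor Ctla4 stood at 0.23 ± 0.15, the transcription factor Ikzf2 at 0.22 ± 0.12 and Tnfrsf18 (GITR) at 0.16 ± 0.15. Their limma adjusted p ran from 0.424 to 0.606, and Tnfrsf18 was -0.03 in the pair of replicates 1 and 2 and 0.35 in the pair of 3 and 4.

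Markers of other cells were unevenly spread over the libraries. The neutrophil genes S100a8 and S100a9 were at 81.2 and 110 FPKM in cKO at 48 h and at 75.9 and 90.7 in cKO 2 at 72 h. Both were listed at 0 in Het 3 and cKO 4, and neither exceeded 0.202 in Het 1 at either time. Lyz2, a myeloid lysozyme, was 36.3 and 24.7 in the same libraries labelled cKO, and the globin gene Hbb-bs 12.6 and 9.13. Another globin gene, Hba-a1, went the other way at 72 h, with 19.1 in Het 1 against 7.58 in cKO 2 and 4.68 in Het 3 against 0 in cKO 4. The B cell gene Pax5 reached 25.2 in cKO 2 at 72 h, against 0.05 in cKO 4. Cd8a was 20.3 and 39.0 in Het 1 and cKO 2 at 72 h, and at most 2.24 in Het 3 and cKO 4.

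**Figure D2:**
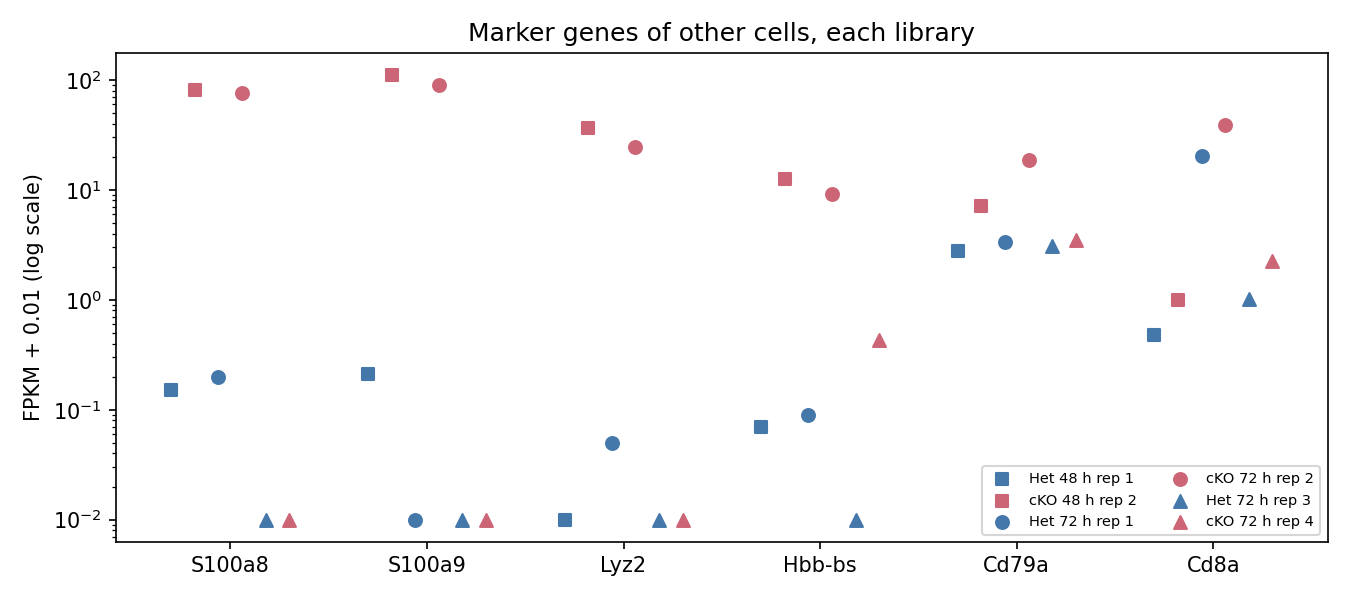
FPKM plus 0.01 on a log axis for 6 marker genes of neutrophils and other myeloid cells (S100a8, S100a9, Lyz2), red cells (Hbb-bs), B cells (Cd79a) and CD8 T cells (Cd8a), 1 point per library, with Het in blue and the libraries labelled cKO in red. S100a9 reaches 110 and 90.7 in both cKO libraries numbered 2 and is listed at 0 in cKO 4.

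At 72 h, the libraries labelled cKO held more transcripts of p53 target genes, T cell activation genes and effector cytokines than Het, and fewer of mitotic genes and glycolytic enzymes. The p53 targets had a median log2 fold change of 0.91 and the 36 mitotic genes one of -0.58. These 5 lists passed camera at a preset correlation, while for each of them adjusted p = 0.64 with an estimated correlation. No single gene passed limma's adjusted p of 0.05 among 12488 tested, while 2159 lay under an unadjusted p of 0.05 (1286 higher and 873 lower, with 624 expected by chance). The smallest adjusted p was 0.106. The fit had the table as a term and left 1 residual degree of freedom.

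The genes named as higher were picked by rule for values above those of Het in both pairs, so that agreement is no result. Penk, the precursor of enkephalin peptides, rested at 2.64 and 0.758 FPKM in Het and 38.3 and 26.2 in the libraries labelled cKO, a log2 fold change of 3.69 ± 0.19 (SE, limma adjusted p = 0.106). Serpine2, a serine protease inhibitor, stood at 3.49 ± 0.16 and the interferon-inducible GTPase Iigp1 at 3.59 ± 0.40. Cd74, the invariant chain of MHC class II, stood at 3.39 ± 0.37, with 147 FPKM in cKO 2, where B cell genes peaked, and 27.4 in cKO 4. Ckmt1 (mitochondrial creatine kinase) went from 0.798 and 0.595 FPKM in Het to 16.7 and 9.34. The activation marker Cd83 stood at 2.90, Lad1 at 2.90, the phosphoinositide 3-kinase subunit Pik3r3 at 2.75, the cytochrome c oxidase subunit Cox6b2 at 2.73 and the sulfatase Sulf2 at 2.56.

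The genes named as lower were likewise picked for values below those of Het in both pairs. Stc2, a secreted glycoprotein, was 56.2 and 64.2 FPKM in Het and 5.10 and 8.76 in the libraries labelled cKO, a log2 fold change of -2.98 ± 0.18 (SE, limma adjusted p = 0.106). Pygl, a glycogen phosphorylase, stood at -2.92 ± 0.15, and Igfbp4, which binds insulin-like growth factors, at -2.28 ± 0.14 from 521 and 606 FPKM in Het. The integrin Itga7 stood at -3.28, the collagen prolyl hydroxylase P4ha2 at -3.08, the TGF-beta family receptor Acvrl1 at -2.96, the acyl-CoA synthetase Acsl6 at -2.64, Ggt1 (gamma-glutamyltransferase) at -2.45, the metallothionein Mt2 at -2.44 and Ndrg1 at -2.29.

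Mitotic genes were lower at 72 h in the libraries labelled cKO, 36 of 36 measured members. Of these, 28 passed when adjusted over the list alone and 0 when adjusted over all genes. Top2a, the topoisomerase that untangles replicated DNA, stood at -0.82 ± 0.13 (SE), the proliferation marker Mki67 at -0.80 ± 0.15, Anln at -0.96 ± 0.17 and the checkpoint kinase Bub1 at -0.63 ± 0.12. Camera gave an adjusted p of 1.01e-20 with a preset correlation, and adjusted p = 0.64 with an estimated correlation. Genes of the G1/S transition and DNA replication, by contrast, had a median of 0.04 (22 of 38 higher, adjusted p = 0.726 with the preset correlation, where the test's direction was downward).

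Glycolytic genes were lower too, 19 of 20, with a median of -0.70, and 16 of the lower ones passed adjusted over the list alone. The glucose transporter Slc2a3 stood at -1.51 ± 0.14 (SE), the lactate exporter Slc16a3 at -1.23 ± 0.12 and the aldolase Aldoc at -1.81 ± 0.22. Pdk1, which restrains pyruvate oxidation in mitochondria, stood at -1.14 ± 0.14. Camera's adjusted p was 7.29e-13 with the preset correlation, and adjusted p = 0.64 with an estimated correlation. Of the naive and homing genes, 8 were lower and 1 was higher adjusted over the list alone, with a median of -0.04 and a mean of -0.30. The transcription factors Klf2 and Klf3 stood at -1.37 ± 0.14 and -1.22 ± 0.13. The camera adjusted p was 0.00788 with the preset correlation, and adjusted p = 0.64 with an estimated correlation.

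Targets of p53, the transcription factor that responds to DNA damage and nucleolar stress, were higher in 29 of 32 measured members, and 21 passed adjusted over the list alone. Psrc1 was 29.1 and 27.0 FPKM in Het against 117 and 113 in the libraries labelled cKO, and Phlda3 18.4 in both Het libraries against 78.2 and 74.6. The adenylate kinase Ak1 stood at 2.25 ± 0.19 (SE) and the stress-inducible Sesn2 at 1.77 ± 0.15. The proapoptotic genes Bbc3 (Puma) and Bax stood at 1.44 ± 0.14 and 0.98 ± 0.14. Camera's adjusted p was 1.33e-10 with the preset correlation, and adjusted p = 0.64 with an estimated correlation.

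**Figure D3:**
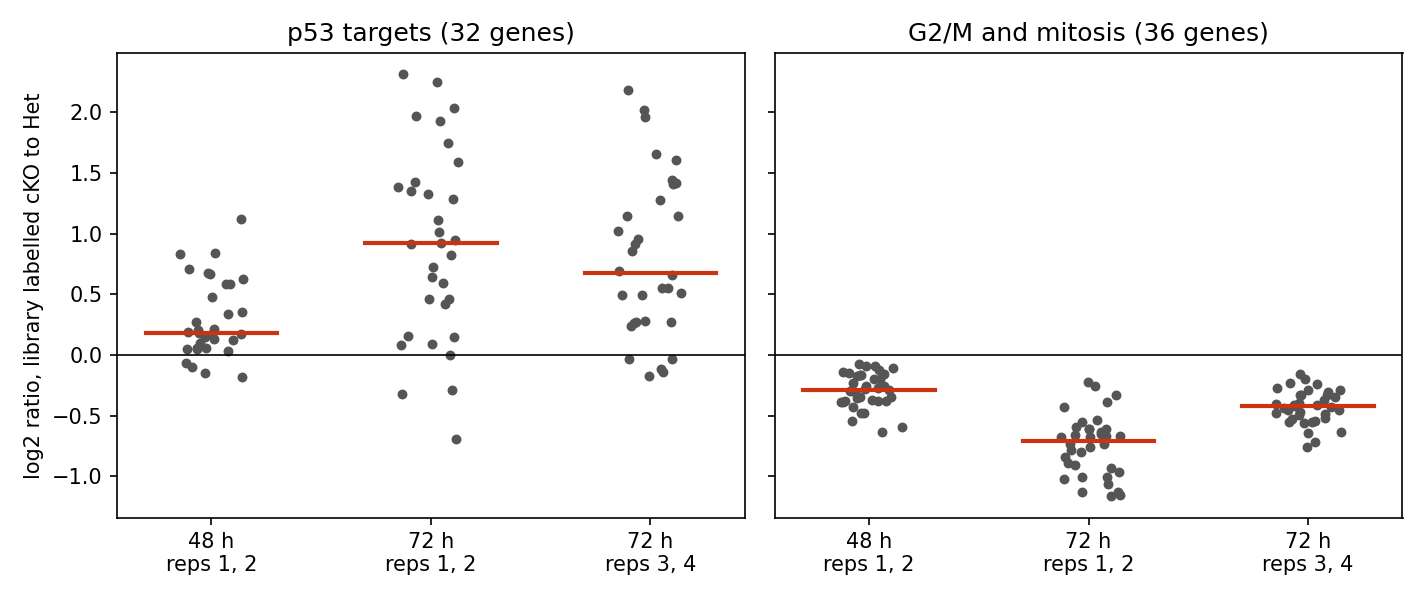
Log2 ratio of FPKM + 1 in the library labelled cKO to Het, for each of 32 p53 targets (left) and 36 mitotic genes (right) in the 3 pairs of libraries, with 1 grey point per gene and a red line at the median. The p53 medians are 0.18 at 48 h, 0.92 in replicates 1 and 2 at 72 h and 0.68 in replicates 3 and 4, and the mitotic medians are -0.28, -0.71 and -0.42.

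T cell activation genes were higher in 32 of 33 members, with a median of 0.85, and 18 passed adjusted over the list alone. The nuclear receptor Nr4a3, induced by antigen receptor signalling, stood at 2.78 ± 0.27 (SE), the transcription factors Irf4 and Irf8 at 1.40 ± 0.12 and 2.05 ± 0.23, and the survival gene Bcl2l1 at 1.66 ± 0.18. Effector cytokines and factors were higher in 16 of 21, with a median of 1.34, and adjusted over the list alone 15 passed as higher and 1 as lower. Ifng (interferon gamma) stood at 2.72 ± 0.26, Tbx21 (T-bet), which drives it, at 2.74 ± 0.27, the chemokine Ccl4 at 2.07 ± 0.23 and Eomes at 1.93 ± 0.20. Camera's adjusted p was 1.56e-10 and 4.35e-05 with the preset correlation, and for both lists adjusted p = 0.64 with an estimated correlation.

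Interferon-stimulated genes were higher in 20 of 22, with a median of 0.45, and 5 passed adjusted over the list alone. The GTPase Irgm1 stood at 1.67 ± 0.19 (SE) and the antiviral membrane protein Bst2 at 1.27 ± 0.19. The CD8 T and NK cell markers were higher in 8 of 8, among them the granzyme Gzma at 2.68 ± 0.22 and Nkg7 at 2.95 ± 0.35, and 6 passed adjusted over the list alone. Cd8a itself, uneven between the tables, stood at 0.80 ± 0.15. Camera's adjusted p was 4.35e-05 for each of these lists with the preset correlation, and adjusted p = 0.64 with an estimated correlation.

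Ribosome assembly genes rested on 1 pair of libraries. The small subunit processome list was higher in 47 of 50 members, with a median of 0.39, and the large subunit assembly list in 46 of 49, with a median of 0.45. In the pair of replicates 1 and 2 the medians were 0.79 and 0.88, and in the pair of 3 and 4 they were 0.04 and 0.04. None of their genes passed adjusted over the list alone; Pno1 stood at 1.11 ± 0.38 (SE), Wdr12 at 0.69 ± 0.23 and Mdn1 at 0.95 ± 0.34. Camera gave an adjusted p of 0.000266 and 0.000199 with the preset correlation, and adjusted p = 0.74 with an estimated correlation. The RNA polymerase I and III list had a median of 0.14 (adjusted p = 0.208), and the cytosolic ribosomal proteins a median of 0.01 and a mean of -0.01 (adjusted p = 0.211).

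Other lists passed at the preset correlation as well. Cholesterol synthesis genes had a median of -0.15 (16 of 23 lower, adjusted p = 0.000377). Histone genes stood at -0.25 over 16 members (adjusted p = 0.00765). The 5 of them with a mean of at least 5 FPKM had a median of 0.05 in the pair of replicates 3 and 4. Mitochondrially encoded genes stood at 0.65 (adjusted p = 0.00976), oxidative phosphorylation at 0.15 (adjusted p = 0.0421) and Myc targets with amino acid transport at 0.28 (adjusted p = 0.0472), where Odc1, which makes polyamines, stood at 1.07 ± 0.13 (SE). The stress response list had a median of 0.30 (adjusted p = 0.0478), with Cebpb at 1.60 ± 0.23 but Trib3 at -2.14 ± 0.15 and Vldlr at -1.90 ± 0.22. Myeloid and B cell markers had medians of 1.61 (adjusted p = 0.00992) and 1.13 (adjusted p = 0.0198). Over members with a mean of at least 5 FPKM, several of these medians differed between replicates 1 and 2 and replicates 3 and 4, at 0.60 and 0.02 for Myc targets, 2.58 and 0.11 for myeloid markers, 0.75 and 0.15 for B cell markers and 1.03 and 0.32 for mitochondrially encoded genes. With an estimated correlation the adjusted p of these lists ran from 0.64 to 0.74.

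The regulatory T cell signature had a median of 0.24 at 72 h (24 of 33 higher, adjusted p = 0.052), and adjusted over the list alone 6 members passed as higher and 1 as lower. The chemokine receptor Ccr8 stood at 1.46 ± 0.16 (SE) and Tnfrsf9 at 0.84 ± 0.12. The list's median was -0.01 in the pair of replicates 1 and 2 and 0.47 in the pair of 3 and 4. Apoptosis regulators (median 0.19, adjusted p = 0.11) and erythroid and platelet markers (4 of 6 higher, adjusted p = 0.538) did not pass. In all, 18 of 24 lists passed with the preset correlation and 0 with an estimated one. The estimated run rests on 1 residual degree of freedom, which leaves it little power. For the naive and homing genes the estimated correlation was -0.013, below the preset 0.01. Camera's unadjusted p for them still went from 0.00394 to 0.194. For this list, loss of the call thus does not show that correlation between genes removed it. The estimate was also below the preset for interferon-stimulated genes (-0.039) and cholesterol synthesis (-0.043). It was far higher for the mitotic genes (0.784) and both ribosome assembly lists (1), so their preset p-values assume much less correlation than was estimated. The p53 targets had 0.069. These estimates rest on 1 residual degree of freedom as well.

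**Figure D4:**
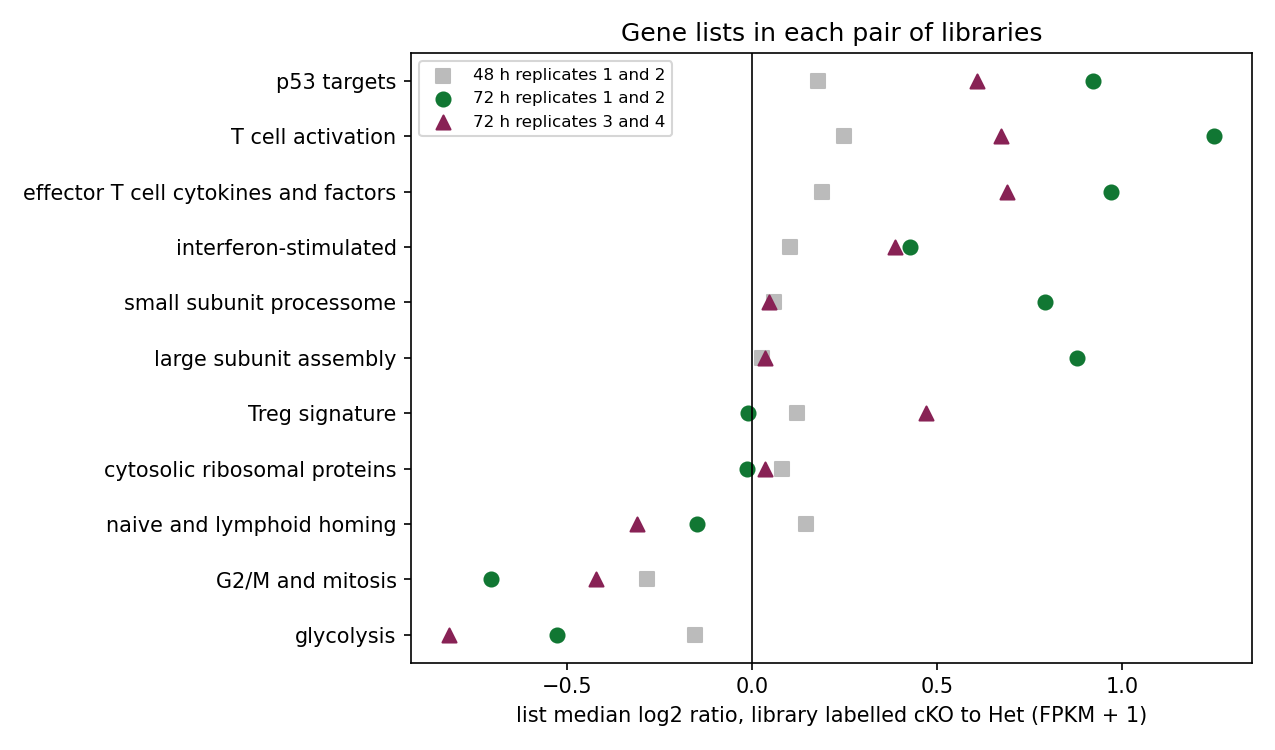
Median log2 ratio (horizontal axis, FPKM + 1, library labelled cKO to Het) of 11 gene lists (rows) in each pair of libraries, over members with a mean of at least 5 FPKM, with squares for 48 h, circles for replicates 1 and 2 at 72 h and triangles for replicates 3 and 4. The p53 targets lie above 0 and the mitotic and glycolytic genes below 0 in each pair, while the 2 ribosome assembly lists are at 0.79 and 0.88 in replicates 1 and 2 only.

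Averaged over both times, with 3 libraries per genotype, the same lists led. Mitotic genes were lower in 36 of 36 members in the libraries labelled cKO (median -0.50), and 33 passed adjusted over the list alone. The p53 targets were higher in 29 of 32 (median 0.66, 15 adjusted over the list alone). Of the genes named by rule for this comparison, the MHC class II gene H2-Eb1 stood at 2.51 ± 0.41 (SE), Tbkbp1 at 1.70 ± 0.22, Rgs16, a brake on G protein signalling, at 1.58 ± 0.22, Ltf (lactoferrin) at 1.48 ± 0.14 and Bbc3 at 1.33 ± 0.13. Selenbp1 stood at -1.67 ± 0.27, Aldoc at -1.44 ± 0.28, the interleukin 18 receptor Il18r1 at -1.38 ± 0.30, Unc13a at -1.21 ± 0.23 and Arrb1 at -1.16 ± 0.20.

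No gene passed limma's adjusted p of 0.05 over both times among 12394 tested, and 1650 lay under an unadjusted p of 0.05 (996 higher, 654 lower, 620 expected by chance). The smallest adjusted p was 0.343. Camera called 19 lists with the preset correlation, led by the mitotic genes (adjusted p = 8.55e-27), glycolysis (adjusted p = 1.99e-12) and the T cell activation genes (adjusted p = 3.67e-11). With an estimated correlation camera gave each of these, and the p53 targets, adjusted p = 0.407, and none of the 19 passed. Without either library of the pair of replicates 3 and 4, 7 genes passed, all higher in the libraries labelled cKO. They were the neutrophil genes S100a9, S100a8, Ngp, Camp, Lcn2, Chil3 and Lyz2.

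At 48 h there was 1 library per genotype and no test. The 10 highest log2 ratios of the library labelled cKO to Het were led by S100a9 (6.53), S100a8 (6.17), Ngp (5.79) and Lyz2 (5.22), all made by neutrophils or other myeloid cells. Camp (4.34), Lcn2 (4.32) and Chil3 (3.69) are myeloid products as well, while Shd (4.53) and Vcp-rs (3.86) were under 0.5 FPKM in each of the other 5 libraries. Anxa1 (3.71) did not follow the neutrophil genes, with 7.49 FPKM in Het 1 and 3.41 in Het 3 at 72 h, where S100a9 was listed at 0. Most of the 10 lowest were T cell receptor joining segments, Traj26 (-2.04), Traj9 (-1.75), Traj30 (-1.35), Traj20 (-1.29), Traj37 (-1.28) and Traj25 (-1.21), short genes with few fragments. The others were the pseudogenes Rpl3-ps1 (-2.38), Rbpj-ps3 (-1.48) and Rps2-ps10 (-1.30), whose reads can be shared with their parent genes, and Ighj2 (-1.16).

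Fewer genes differed between genotypes at 48 h than in either 72 h pair. Of 9084 genes with a mean of at least 5 FPKM, 50 were at least 2-fold higher and 30 at least 2-fold lower in the library labelled cKO. The pair of replicates 1 and 2 at 72 h had 385 and 325 of 9257, and the pair of 3 and 4 had 217 and 131 of 9386. The mitotic list had a median of -0.28 at 48 h, below all of 10000 random lists of matched expression, with 36 of 36 lower. The p53 targets had a median of 0.18 (26 of 30 higher) and the T cell activation genes 0.25, both at percentile 100. Cholesterol synthesis genes (-0.23) and glycolysis (-0.15) lay at percentile 0, and the small and large subunit lists at 0.06 and 0.03 (percentiles 97.4 and 78.5). Random lists hold unrelated genes, so genes regulated together reach extreme percentiles more readily, and with 1 library per genotype these are no test of genotype.

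From 48 h to 72 h, 3 genes rose past limma's adjusted p of 0.05 in a fit over both genotypes, and none fell. Gzmb (ENSMUSG00000015437), a granzyme of cytotoxic granules that regulatory T cells also use, rose by a log2 fold change of 4.54 ± 0.29 (SE, adjusted p = 0.0481), from 23.7 to 379 FPKM in Het and from 22.1 to 811 in cKO. Cd8a (ENSMUSG00000053977), the CD8 co-receptor, rose by 4.09 ± 0.20 (adjusted p = 0.0186) and the transglutaminase Tgm2 (ENSMUSG00000037820) by 3.28 ± 0.13 (adjusted p = 0.0124). With the table as a term, the time effect came from the first table alone. In the second table, Cd8a was at most 2.24 FPKM at 72 h, Tgm2 at most 20.7, and Gzmb 182 and 227, and without the table term none of the 3 passed (adjusted p from 0.23 to 0.373). Without either of the 48 h libraries 0 genes passed (smallest adjusted p 0.25 and 0.236).

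Other genes with large values between the times did not pass. Ifitm1 stood at 4.26 ± 0.54 (SE), the metallothioneins Mt2 and Mt1 at 3.80 ± 0.68 and 3.53 ± 0.51, the small nuclear RNA Rn7sk at 2.31 ± 0.18, Trgv2 at 2.43 and Fam19a3 at 2.10, and Tmem176a went from 1.93 to 10.7 FPKM in Het and from 2.05 to 10.5 in cKO. The early response genes Fosb and Fos stood at -3.20 ± 0.96 and -1.63 ± 0.30, and the Notch regulator Dtx1 at -2.12 ± 0.42. Klf4 was 12.7 and 20.5 FPKM at 48 h and 1.27 and 7.15 at 72 h in Het 1 and cKO 2. Stra6 stood at -2.12, B9d1 at -1.56, the receptor regulator Lrig1 at -1.20, the RNA-binding Zfp36l1 at -1.16 and mt-Atp8 at -1.24. Tpm3-rs7, a copy related to Tpm3 whose reads may be split with it, stood at -4.08. In all, 1374 of 12394 genes lay under an unadjusted p of 0.05 (800 higher, 574 lower).

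Between the times, the CD8 T and NK cell markers were higher in 8 of 8 members (median 2.02), and 7 passed adjusted over the list alone, among them Prf1 (perforin) at 1.67 ± 0.18 (SE). Interferon-stimulated genes were higher in 21 of 22 (median 0.37, 7 adjusted over the list alone), with the RNA sensors Ddx58 and Dhx58 at 0.78 ± 0.14 and 0.93 ± 0.17. Replication genes were lower in 37 of 38 (median -0.26), with Mcm7 at -0.44 ± 0.12 and Gins2 at -0.56 ± 0.15, and 0 passed adjusted over the list alone. With camera the adjusted p was 4.83e-10, 3.53e-06 and 1.26e-08 with the preset correlation, and adjusted p = 0.709 with an estimated correlation for each.

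Small and large subunit assembly genes were lower at 72 h, 47 of 50 and 48 of 49 (medians -0.34 and -0.33, adjusted p = 1.01e-06 for both). The lower values lay in Het, with medians of -0.72 and -0.76, and in cKO the medians were 0.07 and 0.09. Cytosolic ribosomal proteins (median -0.15), Myc targets (-0.30), mitochondrially encoded genes (-0.36), T cell activation (-0.39), oxidative phosphorylation (-0.12) and histones (-0.16) also passed as lower, and glycolysis (0.20) and effector factors (0.48) as higher. Some of these also lay mostly in Het, with medians in Het and cKO of -0.56 and 0.00 for Myc targets, -0.89 and 0.06 for mitochondrially encoded genes, -0.86 and -0.10 for T cell activation and 0.48 and 0.00 for glycolysis. Effector factors (0.075 and 0.391) and cytosolic ribosomal proteins (-0.089 and -0.177) moved more in cKO. With an estimated correlation the adjusted p of each was 0.709.

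The genotype effect was not shown to differ between 48 h and 72 h for any gene. Limma's interaction term gave 0 of 12394 genes, with a smallest adjusted p of 0.742 and 708 genes at an unadjusted p under 0.05 (620 expected by chance). Camera called 12 lists on this term with the preset correlation, led by glycolysis (median -0.55, adjusted p = 1.48e-08), the mitotic genes (-0.28) and the p53 targets (0.64), and adjusted p = 0.817 was found for each of the 12 with an estimated correlation. In simulated data with this design, 4% of genes with a log2 change of 2 were recovered on the interaction term and 58% of those with a change of 4.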

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

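The tests on the course over time, on a shared library and on transcripts of other cells were chosen after the results they measure were seen, and those on scaling and on counting error before. Camera's interaction test, with a preset correlation, marked 12 lists whose genotype effect differed between 48 h and 72 h. The effect at 72 h was more negative for glycolysis (adjusted p = 1.48e-08), mitotic genes (4.02e-07), naive and homing genes (2.43e-05), cytosolic ribosomal proteins (0.00345) and histones (0.0197). It was more positive for p53 targets (6.06e-07), T cell activation (1.16e-05), effector factors (0.00117), interferon-stimulated genes (0.00138), CD8 T and NK cell markers (0.00322), large subunit assembly (0.0059) and the small subunit processome (0.0135). With an estimated correlation each had adjusted p = 0.817.

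Among the genes named for every library or for genotype at 72 h, 8 had one sign in both pairs at 72 h and the other sign in the 48 h pair, a difference with no call in the interaction test. Their 48 h log2 ratios were -0.20 for Ctla4, -0.16 for Ikzf2, -0.41 for Iigp1, -0.07 for Lad1, 0.76 for Pygl, 0.20 for Mt2, 0.26 for Igfbp4 and 0.08 for Ggt1. No group had 4 or more libraries, so no library was tested for standing apart from its group.

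Across genes, the 72 h ratio of the library labelled cKO to Het ran opposite to the change of Het from 48 h to 72 h, with r = -0.755 for replicates 1 and 2, which share Het 1 at 72 h with that change. The pair of replicates 3 and 4, which shares no library with that change, gave r = -0.377 over 9284 genes, but genes are not independent and 1 pair of libraries keeps chance variation between libraries open. Among genes with a mean of at least 50 FPKM, replicates 3 and 4 gave r = -0.379 (upper limit -0.309, from a bootstrap over genes). Counting error arises in each library by itself, so it cannot give r in a pair that shares no library. Its part in r = -0.755 for replicates 1 and 2 stays open, since that pair was not tested among such genes. A slower course of the Het change may underlie the opposite direction as a hypothesis and stays open, mitotic genes included. Their median went by -0.191 from 48 h to 72 h in the libraries labelled cKO and by 0.24 in Het, with 1 library at each time.

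The p53 targets were higher at 72 h in the libraries labelled cKO, and transcripts of other cells stay open for both pairs, with medians over members with at least 5 FPKM of 0.919 in replicates 1 and 2 and 0.607 in replicates 3 and 4. S100a8, S100a9 and Lyz2 were at 0 in replicates 3 and 4. Of 9 markers of other cells at 5 FPKM or more there, 3 (Gzma, Nkg7 and Cd68) were at least 2-fold higher in cKO 4. Ifng and Tbx21 of the effector list were higher there too (log2 ratios 2.385 and 2.286), so the sorted cells themselves may hold Gzma and Nkg7. Cd8a was 2.24 FPKM in cKO 4, against 89.1 for Nkg7. The count of markers thus cannot tell other cells from the sorted ones. Scaling between libraries is argued against, since the p53 list stood above random lists of matched expression under each of 4 scalings. The smallest median, with quantile normalization, was 0.782 against an upper limit of 0.124 for random lists. A shift shared by all genes moves both values, so only the gap between them bears on this. From 48 h to 72 h the median changed by 0.439 in the libraries labelled cKO and by -0.106 in Het. A slower course of the Het change would by itself give no such rise. It stays open only because each value rests on 1 library at each time. An effect of the genotype itself stays open and could not be weighed beyond this, given the direction of Noc4l.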

How the results depend on the processing

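The replicate block, leaving out single libraries from the list tests, the list medians of single pairs and the removal of 16 genes high in both libraries labelled cKO 2 and not in cKO 4 were chosen after the data were seen. A replicate block was possible for time alone (numbers 1 and 2), since the genotypes share no replicate number. With the replicate number as a block, the count of 3 for time was 0 (smallest adjusted p 0.0588), with the same fold changes and 1 residual degree of freedom. The labels do not say that a number marks 1 animal, and numbers 1 and 2 are also the genotypes, so their deviations (r = 0.301 between the 48 h and 72 h ratios) do not show pairing. Leaving out a library ends the 72 h and interaction tests, with no residual degrees of freedom, so those gave values with no test. The count of 0 for genotype at 72 h became 8 with no filter on low values (adjusted p = 0.0466 for each), and was 0 under the other tested settings. Over both times it was 0 except for 0 to 7 when each library was left out, and 0 without the 16 genes. The count of 3 for time was 1 with a pseudocount of 5, 2 with quantile normalization, median centring or no variance trend, 0 with no filter, 0 with no table term and 0 to 4 when each library was left out (0 without either 48 h library, 1 without Het 1 at 72 h). The interaction count was 0 throughout. At 48 h, 80 genes differed at least 2-fold, 47 with a pseudocount of 5, 240 at a mean of 1 FPKM and 27 at a mean of 20. Of the 18 lists at 72 h and 19 over both times, 0 and 0 passed with an estimated correlation and 0 and 1 with fry, and over both times 14 to 20 when each library was left out. With no table term 14 and 15 passed. Myc targets (0.0756 and 0.0764), oxidative phosphorylation (0.221 and 0.101), the stress response (0.168 and 0.0584) and mitochondrially encoded genes (0.102 and 0.0584) were lost in both, and B cell markers (0.0683) at 72 h. The regulatory T cell signature passed at 72 h with no table term (0.0462) or median centring (0.0291), where oxidative phosphorylation (0.085) did not. The large subunit list over both times had adjusted p from 3.03e-11 to 0.976, with the direction turned without either library of replicates 1 and 2 at 72 h. With 1 pair at 72 h, Tnfrsf18 ran from -0.028 to 0.353. Over members with a mean of at least 5 FPKM, the median of cytosolic ribosomal proteins ran from -0.014 to 0.035. That of the regulatory T cell signature ran from -0.013 to 0.468 and that of histones from -0.518 to 0.054. The cause was not tested, beyond the genes and libraries each setting adds or removes. Depth sets counting error only, and the number of libraries limits these comparisons.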

Other observations

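The test of other splits of the libraries and the test of scaling were set before their results were seen, and the other tests on Noc4l after. Every library held both Xist and Y-linked transcripts. The X-inactivation RNA Xist was 76.3 and 89.1 FPKM in Het and cKO at 48 h, 107 and 55.9 in replicates 1 and 2 at 72 h, and 165 and 113 in replicates 3 and 4. The Y-linked translation factor Eif2s3y was 48.0 and 33.2, then 33.8 and 67.5, then 32.5 and 59.4. In both 72 h pairs Xist was lower and Eif2s3y higher in the library labelled cKO, and at 48 h the reverse held. Both genes thus ran with the genotype labels at 72 h, and whether the make-up by sex bears on other 72 h differences was not tested.

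The library labelled cKO 2 at 72 h lay closer to the 48 h libraries than its Het partner did. Across 9284 genes its correlation with Het at 48 h was r = 0.969 and with cKO at 48 h 0.973, against 0.941 and 0.926 for Het 1 at 72 h. The other 72 h pair differed little, with 0.911 and 0.9 for cKO 4 against 0.908 and 0.891 for Het 3. From 48 h to 72 h, 349 genes were at least 2-fold higher in Het and 195 in the libraries labelled cKO, and 211 and 51 at least 2-fold lower. Genes are not independent replicates, and these values were not tested.

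Noc4l was higher in the library labelled cKO in 3 of 3 pairs. Scaling between libraries is argued against, since the smallest log2 ratio over the pairs and 4 scalings was 0.286, with a counting limit of 0.206. Transcripts of the recombined allele may still be counted, and with 1 value per gene (log2 fold change 0.62 at 72 h) the tables cannot tell this apart from exchanged labels. An exchange of labels in 3 of 3 pairs would give the same values.

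The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 1650 genes at an unadjusted p under 0.05 and the highest other split 2209, so 3 of the 10 splits gave as many. Both splits above the real one hold the same contrast once time and table are fitted, that of Het 1 and cKO 2 at 72 h. Of the 4 splits with 1 library of each pair on either side, the other 3 gave 136, 107 and 612. For lists past the threshold the real split gave 19 and the highest other 18, and 1 of the 10 splits, the real one, gave as many.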
